A study of Mus musculus with 24 samples.

How the data were processed

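Total RNA from lung kept in RNAlater was extracted with TRIzol, and poly(A) RNA selected with oligo(dT) was made into strand-specific libraries, per the labels' protocols. Reads were checked with FastQC 0.12.1, trimmed with fastp 0.23.4 and aligned to GRCm39 with STAR 2.7.11b, and featureCounts gave the counts per gene, per the submitters' processing notes. The same notes name R 4.4.1 and DESeq2 for the authors' own tests. The deposited table holds whole-number read counts for 78275 genes in 24 libraries, with no scaling. The annotation release, the strand setting of the counting and the handling of reads with several matches are not given in the sources used here, so antisense, overlapping and near-identical genes, among them the ribosomal protein, globin and immunoglobulin families, carry uncertain counts.

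Gene symbols came from an annotation of the earlier build GRCm38, matched by gene identifier and used for names, gene types and exon lengths only. Of the 78275 genes, 51486 had a symbol, and these held 98.45% of the counts. Columns were assigned to the 8 groups of 3 by their labels, and all 24 were used. The batch of each library is the date in its label: 9 in March, 14 in October and 1 in November. Whether it is the date of collection, extraction or sequencing is not given in the sources used here, so the batch term can stand for any of them. Total counts ran from 12224106 to 16925635 in March and from 3906807 to 11298160 in October, with 18494156 in the November library. No pair of libraries in a group was a copy: chi-square per gene between them was 6.72 to 271.9 over 12669 genes.

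Counts were tested in R 4.3.3 with edgeR 4.0.16, after edgeR's filter on low counts, which left 17490 genes, and TMM scaling. All 24 libraries went into a quasi-likelihood model with terms for batch and group, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with their standard errors, and counts scaled to library size (CPM) as means with SD over 3 libraries or per library. The 13 comparisons were DE and RIC against C, each of the 5 treated groups against DE, each pirfenidone group with conditioning against DE+PFD, the timings of conditioning without and with pirfenidone, and the interactions of pirfenidone with each timing. Written before the data were examined were the groups, comparisons, tests, threshold, gene lists, readout genes, the rule for named genes and the alternatives, except those said below to be later.

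Named genes were to be those with the largest changes past the threshold at a mean of at least 1 CPM, or, where none passed, the 4 with the smallest p, leaving out predicted genes, pseudogenes and antigen receptor segments. To these come the 3 members with the smallest p in the direction of each list called, and 15 readout genes of fibrosis, inflammation and the response to exhaust in the 7 main comparisons. The text prints a part of them. The 42 gene lists, for cell types and responses, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes. A list was called at an adjusted p under 0.05 over the 42 lists. The same test with a correlation estimated from the data, and the rotation test fry, were run beside it. Camera with an estimated correlation called 0 of the 42 lists in each of the 13 comparisons, and fry called 0 in a given direction. Members past the threshold when adjusted over the list alone are counted apart. A list's median is that of its members' log2 fold changes.

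The covariance of fold changes between DE minus C and each treated group minus DE was set beside 20 data sets simulated from the same means, spreads and library sizes with no group effect, since the DE libraries enter both. Its error comes from leaving libraries out in turn. edgeR and camera (some comparisons) and the covariance were tested on simulated counts. Principal components used log2 CPM (prior count 2).

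The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter and a filter of CPM 1 in 3 libraries, no batch term, the November library put in the October batch, October libraries alone, the libraries of the compared groups alone, the replicate number as a block with and without the batch term, and each library left out in turn. DESeq2 was run on all genes with a count, with its own filtering, so it can call genes that edgeR's filter removed. Chosen after the values were seen were limma with quality weights, March libraries alone, the covariance error and the mean number of called lists. So was the fit without RIC+DE+PFD 1 and DE 1 (below, both libraries that stood apart). It kept RIC+DE 1, at -62.2 on component 1. The gene lists were rerun with no batch term, with the November library in October, with October libraries alone (10 of the 13 comparisons, as RIC+DE has none there), with the block and the batch term, with quality weights, without both libraries that stood apart, without each library in turn and with the estimated correlation, and under no other alternative. In October libraries alone DE+PFD+RIC has 1 library, which is assumed to vary like the other groups. The estimated correlation ended every list call. Calls said below to hold or end under the settings run for lists are therefore judged with it left aside. Nothing was realigned, since no reads were used.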

Results

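Lungs of male C57BL/6 mice, 20 weeks old per the labels, were profiled by poly(A)-selected, strand-specific RNA sequencing. The series asks whether remote ischemic conditioning, short cycles of blocked and restored blood flow in a limb, changes lung fibrosis caused by diesel exhaust. The 24 libraries form 8 groups of 3. C stands for healthy controls and RIC for healthy mice given conditioning on the left leg (3 cycles of ischemia and reperfusion, 5 min each, on 3 days of each of 4 weeks). DE mice breathed diesel exhaust (30 min per day, 5 days per week, about 8 weeks). DE+PFD mice also took pirfenidone, an antifibrotic drug, by mouth at 300 mg/kg per day on 6 days per week, in 0.5% carboxymethylcellulose. None of the 8 groups is labelled as given that vehicle without the drug, so differences between groups with and without pirfenidone cover both. RIC+DE mice were conditioned before the exposure (preconditioning) and DE+RIC mice during it (perconditioning). RIC+DE+PFD and DE+PFD+RIC mice had the same treatments with pirfenidone added. The labels give 3 batch dates, without saying what was done on them. March holds 9 libraries, October 14 and November 1.

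The total counts of the 3 libraries were 15975293, 7789841 and 8882332 in C, 16232624, 7041947 and 8125006 in RIC, and 8885406, 6920161 and 5700391 in DE. They were 14356904, 3906807 and 9446217 in DE+PFD, 13483886, 12437106 and 16925635 in RIC+DE, and 11271432, 7296425 and 18494156 in DE+RIC. RIC+DE+PFD had 12224106, 11298160 and 9172489, and DE+PFD+RIC had 12384143, 14625860 and 7756027. The 3 RIC+DE libraries are all from March and the 3 DE libraries all from October, so these groups share no batch. The first principal component, 28.5% of the variance, set RIC+DE+PFD library 1 apart at a score of 120.9. Its 100 most abundant genes took 39.6% of the counts, and its ribosomal protein genes lay 2.07 log2 units above the mean of the 24 libraries. DE library 1 had the highest score on the second component, 63.8, with 11.1% of the variance.

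**Figure D1:**
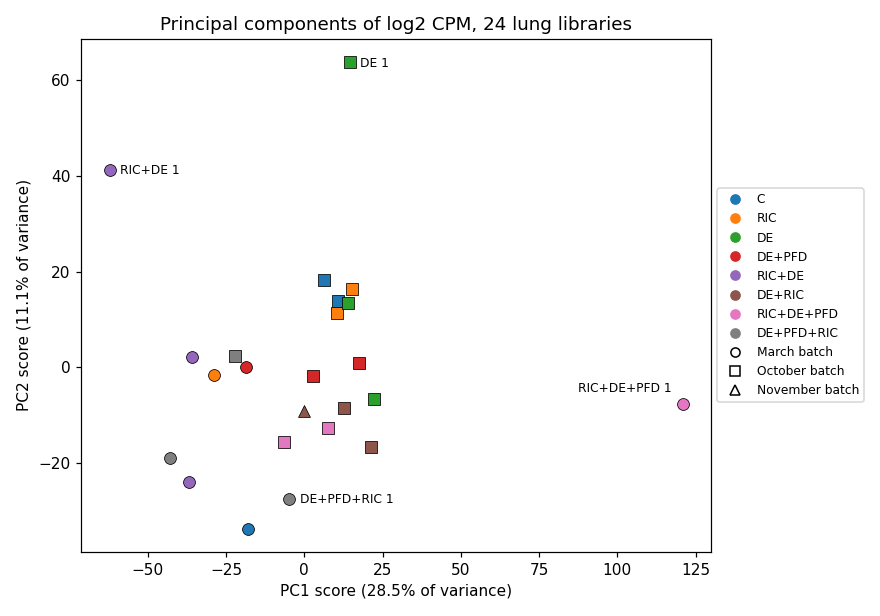
Scores of the 24 lung libraries on the first 2 principal components of log2 CPM, with colours for groups and marker shapes for batches. RIC+DE+PFD 1 sits at 120.9 on the first axis and DE 1 at 63.8 on the second.

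Diesel exposure against healthy lungs. The DE lungs held more transcript of fat cell and mast cell genes by the list test given below, and both lists lay higher in DE libraries 1 and 3 than in DE library 2. Among single genes none passed the threshold. Cd209b, a lectin of macrophages in lymphoid tissue, was at 37.3 ± 39.8 CPM in DE and 1.24 ± 0.34 in C (SD, n = 3), with 80.1, 1.34 and 30.6 CPM in the 3 DE libraries. Timd4, a receptor for dying cells on resident macrophages, was higher by log2 3.49 ± 0.63 (SE), Pla2g2d, a secreted phospholipase, by 2.94 ± 0.56, and Stab2, a scavenger receptor of sinusoidal endothelium, by 2.49 ± 0.51. The edgeR adjusted p was 0.183 for Cd209b and Timd4, 0.235 for Pla2g2d and 0.315 for Stab2. The genes read as measures of fibrosis showed little difference: Col1a1, a chain of the main fibrillar collagen, was at 281.4 ± 89.8 CPM in DE and 344.6 ± 59.3 in C (SD, n = 3).

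Among the gene lists, the 9 adipocyte genes were all higher, with a median log2 change of 1.90, and camera with a preset correlation gave an adjusted p of 4.44e-08 (adjusted p = 0.607 with an estimated correlation). Of these, 8 were higher when adjusted over the list alone and 0 over all genes tested. Cidea, a lipid droplet protein, was higher by log2 4.49 ± 1.40 and Cfd, the complement factor made by fat cells, by 2.19 ± 0.75. The mast cell, basophil and eosinophil list had a median of 1.74 (camera adjusted p = 5.3e-06, and adjusted p = 0.567 with an estimated correlation), with 4 of 7 genes higher when adjusted over the list alone. The mast cell proteases were its leading genes, Mcpt4 at log2 2.80 ± 0.71, Tpsb2 at 3.92 ± 1.02 and Cma1 at 2.05 ± 0.65. Mitochondrially encoded mRNAs had a median of 0.83, with mt-Atp6 at 1.52 ± 0.61, and ribosomal protein genes one of 0.40, with all 24 above 0 (camera adjusted p = 7.42e-08 and 9.87e-06). For these, adjusted p = 0.607 and 0.691 with an estimated correlation. Across genes, which are not independent replicates, Spearman's rho of a library's deviation (log2 CPM from the median of the 24 libraries) with gene length was -0.307 to -0.21 in DE, and 0.328 in the March library of C against -0.167 and -0.271 in its October ones. With the length trend removed, ribosomal protein deviations of 0.287, 0.357 and 0.163 in DE were 0.048, 0.275 and 0.097, and those of -0.253, -0.106 and 0.025 in C were -0.119, -0.154 and -0.036. Those 4 calls held in each fit without 1 library, but without DE library 1 the adipocyte median was 1.12 and the mast cell median 0.90. The T cell list had a median of 0.59, with Trac, the constant chain of the T cell receptor, at 1.05 ± 0.30 and 1 gene higher when adjusted over the list alone (camera adjusted p = 1.94e-06, and adjusted p = 0.691 with an estimated correlation). Without DE library 1 the T cell median was 0.14 and the proliferation median, 0.31 with all libraries, was 0.12, both no longer past camera's threshold. The heat shock list had a median of 0.75, which was 0.30 and past no threshold without DE library 3. In the same list test the unfolded protein response had a median of 0.26, cardiac muscle 0.66, mesothelium 0.38, glucocorticoid response 0.26, smooth muscle and myofibroblast 0.32, B cell 0.25 and club and secretory epithelium 0.34. The TGF-beta pathway was lower at -0.20, immediate early genes at -0.21 and vascular endothelium at -0.25. These 10 calls, and those of the T cell, heat shock and proliferation lists, ended under at least 1 other setting, and their adjusted p ran from 0.691 to 0.79 with an estimated correlation. Without C library 2 the glucocorticoid median was -0.06, and without C library 1 the cardiac and smooth muscle medians were 0.22 and -0.05. Without DE library 1 the B cell and vascular medians were -0.13 and -0.08. Without DE library 2 immediate early genes were at 0.07 and club and secretory epithelium at 0.14.

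Readout genes of fibrosis and of the response to exhaust did not pass the threshold (edgeR adjusted p of 0.988 or more). Col3a1 differed by log2 0.09 ± 0.36, Fn1, fibronectin, by -0.33 ± 0.31, and Acta2, the smooth muscle actin of myofibroblasts, by 0.35 ± 0.36. Timp1, an inhibitor of matrix proteases, differed by 0.31 ± 0.36, Tgfb1 by -0.17 ± 0.20 and Ccn2 by -0.48 ± 0.31. Cyp1a1 and Cyp1b1, enzymes induced through the aryl hydrocarbon receptor, differed by -0.62 ± 1.26 and 0.94 ± 0.39. Hmox1, heme oxygenase, differed by 0.31 ± 0.24. The cytokine Il6 differed by log2 0.58 ± 0.68, Il1b by -0.21 ± 0.46, Tnf by -0.04 ± 0.57 and Ccl2 by 0.77 ± 0.47. The fibrillar collagen and matrix list had a median of -0.08 (camera adjusted p = 0.741) and the fibroblast list one of -0.01 (adjusted p = 0.865).

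edgeR's quasi-likelihood test placed 0 of 17490 genes past the threshold, with 582 at an unadjusted p under 0.05 (341 higher, 241 lower), while DESeq2, run without the filter on low counts, called 17, of which 10 were among those 17490 genes. Without DE library 2 the edgeR count was 15. On simulated counts for this comparison the test recovered 69.7% of 66 genes changed 4-fold, 7.46% of 67 changed 2-fold and 0% of 67 changed 1.5-fold. Where so few genes change, most changes of 2-fold or less would be missed with these libraries. A change in many genes was not simulated for this test.

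**Figure D2:**
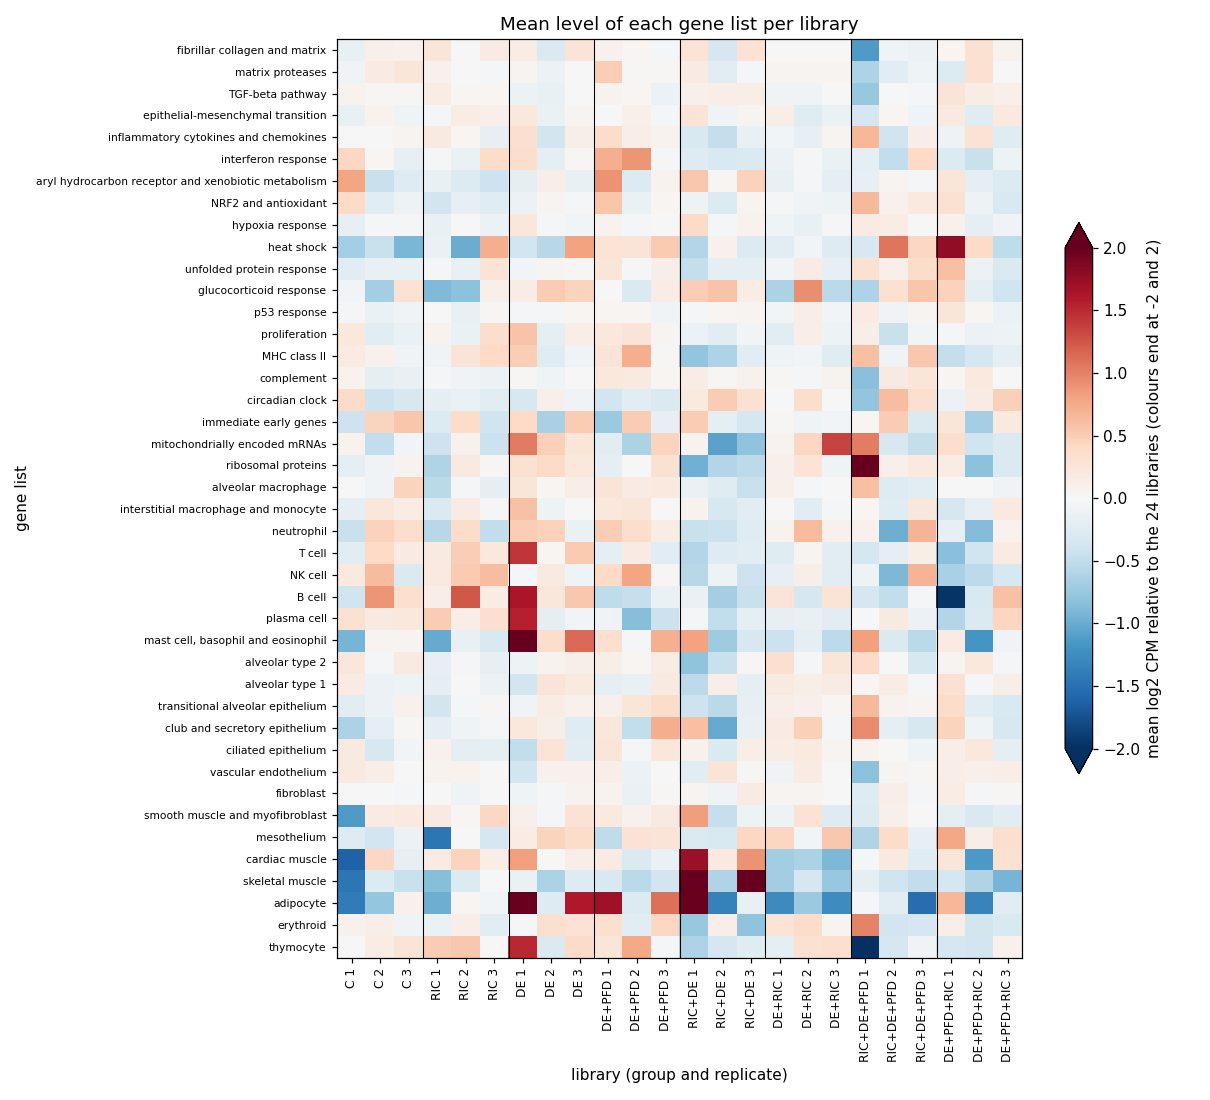
Mean log2 CPM of each of the 42 gene lists in each of the 24 libraries, relative to the mean of all libraries, with colours that end at -2 and 2. The adipocyte list is at 3.58 in DE 1 and the ribosomal protein list at 2.07 in RIC+DE+PFD 1.

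Conditioning in healthy lungs. In RIC lungs the genes of alveolar macrophages and of antioxidant defence were lower than in C, and those of smooth and cardiac muscle were higher, by camera with a preset correlation. The alveolar macrophage list had a median log2 change of -0.38, with 17 of 19 genes below 0 (camera adjusted p = 6.82e-08, and adjusted p = 0.319 with an estimated correlation). Marco, a scavenger receptor of these cells, was at 11.3 ± 3.02 CPM in RIC and 31.3 ± 17.1 in C (SD, n = 3), and Chil3 differed by log2 -1.08 ± 0.40. The NRF2 and antioxidant list had a median of -0.21, with Gsr, glutathione reductase, at -0.51 ± 0.17 and Slc7a11, a cystine transporter, at -1.67 ± 0.73 (camera adjusted p = 2.89e-07, and adjusted p = 0.321 with an estimated correlation).

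Of the 15 lists called, 0 held under every setting run for lists, also with the estimated correlation left aside. Without RIC library 1 the alveolar macrophage median was -0.15 and the NRF2 median -0.07, both no longer past camera's threshold. The cardiac muscle list, median 0.72, and the smooth muscle and myofibroblast list, median 0.46 with Cnn1 at 0.61 ± 0.36, rested on C library 1. Without it their medians were 0.18 and 0.05. For these 2 lists adjusted p = 0.434 and 0.466 with an estimated correlation. Heat shock genes had a median of 0.49 and the unfolded protein response 0.17, and without RIC library 3 these were 0.13 and 0.08. The other calls were alveolar type 2 at -0.19, the aryl hydrocarbon receptor list at -0.16, immediate early genes at -0.27, mesothelium at -0.31, glucocorticoid response at -0.30, neutrophil at -0.42, and T cell, NK cell and B cell at 0.25, 0.25 and 0.23. Among all 15, adjusted p ran from 0.319 to 0.855 with an estimated correlation.

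The 4 genes with the smallest p were Zc3h8 at log2 0.61 ± 0.20, Gsr, Ccl6, a chemokine of myeloid cells that was lower, and Cyp4v3 at -0.55 ± 0.19, each with an edgeR adjusted p of 1. Col1a1 differed by 0.25 ± 0.38, Acta2 by 0.43 ± 0.36, Hmox1 by -0.42 ± 0.24 and Nqo1, a quinone reductase of the NRF2 response, by -0.79 ± 0.47, none past the threshold. edgeR called 0 genes, 209 were at an unadjusted p under 0.05 (106 higher, 103 lower), and DESeq2 called 4, of which 0 were among the genes edgeR tested. Cyp1a1 differed by log2 -2.24 ± 1.30, and C library 1, from March, held 153.3 CPM of it against 7.13 and 6.71 in the other C libraries, from October.

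Pirfenidone in exposed lungs. DE+PFD lungs held less transcript of T cell and B cell genes than DE lungs and more of interferon-induced genes. All 16 T cell genes were lower, with a median log2 change of -0.79 (camera adjusted p = 5.86e-13, and adjusted p = 0.392 with an estimated correlation). Trac differed by -0.95 ± 0.31, and Cd3g and Cd3e, signalling chains of the T cell receptor, by -0.83 ± 0.30 and -0.94 ± 0.34. All 14 B cell genes were lower, with a median of -0.92 and Ms4a1, the CD20 antigen, at -1.02 ± 0.39 (camera adjusted p = 6.67e-11, and adjusted p = 0.478 with an estimated correlation). Of the 21 interferon response genes 18 were higher, with a median of 0.40 (camera adjusted p = 3.84e-07, and adjusted p = 0.479 with an estimated correlation).

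Gbp2, an interferon-induced GTPase, was at 240.7, 359.6 and 110.6 CPM in the 3 DE+PFD libraries and at 87.0 ± 4.11 CPM in DE (SD, n = 3). It differed by log2 1.42 ± 0.45, Gbp3 by 1.49 ± 0.47 and Zbp1, a sensor of nucleic acids, by 1.27 ± 0.48, and 2 genes of the list were higher when adjusted over the list alone. Mitochondrially encoded mRNAs had a median of -0.95, with mt-Nd4 at -0.93 ± 0.41 (camera adjusted p = 2.1e-09, and adjusted p = 0.392 with an estimated correlation). These 4 calls held under each other setting run for lists, but without DE library 1 the T cell median was -0.32 and the B cell median -0.53. The interferon median was 0.24 without DE+PFD library 1 and 0.69 without DE+PFD library 3, and the mitochondrial one -0.59 without DE+PFD library 2. The plasma cell list had a median of -0.76, led by the immunoglobulin gene Ighg2c at -4.09 ± 1.18, with 4 of 10 genes lower when adjusted over the list alone, and the mast cell, basophil and eosinophil list one of -0.95. Without DE library 1 these medians were -0.20 and -0.14, and neither passed camera's threshold. For them adjusted p = 0.392 and 0.758 with an estimated correlation. Ribosomal proteins at -0.28, NK cell at 0.37, MHC class II at 0.22, ciliated epithelium at 0.23 and matrix proteases at 0.21 were also called, with adjusted p from 0.827 to 0.908 with an estimated correlation, and ended under at least 1 setting. Spearman's rho of deviation with gene length was 0.201, -0.0269 and -0.26 in DE+PFD and -0.275, -0.307 and -0.21 in DE. With the length trend removed, ribosomal protein deviations of -0.201, -0.024 and 0.289 in DE+PFD were -0.135, -0.035 and 0.231, and those of 0.287, 0.357 and 0.163 in DE were 0.048, 0.275 and 0.097.

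The smallest p belonged to Cd209b at log2 -4.40 ± 0.84 and Pla2g2d at -3.05 ± 0.58 (edgeR adjusted p = 0.407 for each), Ccl19, a chemokine that draws lymphocytes into lymphoid tissue, at -4.40 ± 0.92, and Timd4 at -2.93 ± 0.62 (adjusted p = 0.585 for each). Cd209b was high in DE libraries 1 and 3 only and low in all others, C included, so its difference here rests on them. Readout genes of fibrosis differed little, Col1a1 by -0.02 ± 0.39, Col3a1 by 0.10 ± 0.36, Acta2 by -0.03 ± 0.37, Fn1 by 0.08 ± 0.32 and Timp1 by -0.07 ± 0.37, each with an edgeR adjusted p of 1. The collagen and matrix list had a median of 0.09 (camera adjusted p = 0.656). In edgeR 0 genes passed the threshold, with 492 at an unadjusted p under 0.05 (213 higher, 279 lower) and 15 calls by DESeq2, of which 5 were among the genes edgeR tested. Without DE library 2 edgeR called 13.

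Preconditioning in exposed lungs. RIC+DE lungs on average held more transcript of muscle genes than DE lungs, and less of ribosomal, erythroid, alveolar type 2 and chemokine genes. Atp2a1, the calcium pump of fast skeletal muscle, was at 264.2, 3.62 and 115.7 CPM in the 3 RIC+DE libraries and at 1.69 ± 0.14 CPM in DE (SD, n = 3). The 7 skeletal muscle genes were all higher, each also when adjusted over the list alone, with a median log2 change of 3.34 (camera adjusted p = 0.00214, and adjusted p = 0.506 with an estimated correlation). The list level was 5.88 and 5.01 in RIC+DE libraries 1 and 3 and -0.61 in library 2. Cardiac muscle genes had a median of 0.78, with Ryr2, the calcium release channel, at 1.99 ± 0.48 and Myh6, the heavy chain of cardiac myosin, at 2.25 ± 0.71 (camera adjusted p = 0.000534, and adjusted p = 0.484 with an estimated correlation).

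Among the lists that were lower, ribosomal proteins had a median of -1.11, with 23 of 24 lower when adjusted over the list alone, and mitochondrially encoded mRNAs one of -1.53, with mt-Co3 at -2.68 ± 0.70 (camera adjusted p = 2.76e-11 and 8.77e-07). The erythroid list had a median of -1.24, with the globin gene Hbb-bs at -1.53 ± 0.51, and the alveolar type 2 list one of -0.63, with Sftpd, surfactant protein D, at -0.82 ± 0.30 (camera adjusted p = 0.000131 and 0.000391). Inflammatory cytokines and chemokines had a median of -0.86, with 20 of 26 genes below 0, 7 of them when adjusted over the list alone, and with Ccl22 at -1.64 ± 0.43 and Ccl4 at -1.95 ± 0.60 (camera adjusted p = 0.000391). For each of these 5 lists, adjusted p = 0.484 with an estimated correlation. These 5 calls and those of both muscle lists held under each other setting run for lists, which do not include October libraries alone since RIC+DE has none, but the ribosomal median was -0.65 without RIC+DE+PFD library 1. Without RIC+DE library 1 the skeletal and cardiac muscle medians were 2.19 and 0.50, and without RIC+DE library 2 they were 5.53 and 1.23. Gene length goes with batch, and so with these groups. Across genes, deviations rose with length in the 8 March libraries other than RIC+DE+PFD 1 (Spearman's rho 0.181 to 0.465, median 0.352), while rho in the 14 October libraries was -0.307 to 0.286 (median -0.208). The RIC+DE libraries, all from March, were at 0.376 to 0.465 and the DE libraries, all from October, at -0.307 to -0.21. With the length trend removed, ribosomal protein deviations of -0.956, -0.619 and -0.555 in RIC+DE were -0.85, -0.384 and -0.434, and those of 0.287, 0.357 and 0.163 in DE were 0.048, 0.275 and 0.097. T cell genes had a median of -0.91, with Trbc2 at -1.64 ± 0.43, which was -0.41 and no longer past camera's threshold without DE library 1. NRF2 genes had a median of -0.35, led by Hmox1 at -0.99 ± 0.29, which was -0.07 with no batch term. Also called were proliferation at -0.45, MHC class II at -0.67, transitional alveolar epithelium at -0.51, unfolded protein response at -0.42, interferon response at -0.38, circadian clock at 0.58 and the TGF-beta pathway at 0.35. These 9 calls ended under at least 1 setting, and adjusted p ran from 0.484 to 0.575 with an estimated correlation.

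Ccl21a, a chemokine of lymphatic vessels, had the smallest p, at log2 -2.32 ± 0.40, beside Atp2a1 at 7.40 ± 1.37, Mybpc2 at 3.71 ± 0.72 and Mylk2 at 5.37 ± 1.08, proteins of skeletal muscle (edgeR adjusted p = 0.237 for each of the 4). Fn1 differed by 0.97 ± 0.37, Timp1 by -1.24 ± 0.43 and Ccl2 by -1.49 ± 0.54 (edgeR adjusted p = 0.274 for each), while Col1a1 differed by 0.64 ± 0.46 and Acta2 by -0.33 ± 0.44. edgeR called 0 genes and DESeq2 80 (77 of them tested by edgeR), and 3006 were at an unadjusted p under 0.05 (1362 higher, 1644 lower). These groups share no batch, and the edgeR count was 102 with no batch term, 18 without DE library 2 and 54 without RIC+DE library 2.

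Perconditioning in exposed lungs. DE+RIC lungs held less transcript of lymphocyte, mast cell, fat and cardiac muscle genes than DE lungs. All 16 T cell genes were lower, with a median log2 change of -0.78, Trac at -1.33 ± 0.35 and Cd4 at -1.64 ± 0.56, and 5 lower when adjusted over the list alone (camera adjusted p = 1.5e-16, and adjusted p = 0.261 with an estimated correlation). All 14 B cell genes were lower, with a median of -0.78 and Spib, a transcription factor of B cells, at -1.27 ± 0.53 (camera adjusted p = 9.82e-10, and adjusted p = 0.416 with an estimated correlation). The adipocyte list had a median of -2.35, with Cidea at -4.88 ± 1.72 and 7 of 9 genes lower when adjusted over the list alone, and the cardiac muscle list one of -1.21, with Tnnt2, cardiac troponin T, at -1.30 ± 0.46 (camera adjusted p = 9.82e-10 for each, and adjusted p = 0.273 with an estimated correlation). The mast cell, basophil and eosinophil list had a median of -1.87, with Tpsb2 at -3.87 ± 1.19 and 5 of 7 genes lower when adjusted over the list alone (camera adjusted p = 2.45e-06, and adjusted p = 0.261 with an estimated correlation).

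These 5 calls held under each other setting run for lists, but without DE library 1 the medians were -0.35 for T cell, -0.39 for B cell, -1.12 for the mast cell list and -1.44 for adipocyte. Ciliated epithelium genes were all higher, with a median of 0.34, but at 0.13 and past no threshold without DE library 1 (adjusted p = 0.273 with an estimated correlation for all libraries). The same library ended the calls of plasma cell genes, -0.49 with and -0.10 without it, of the interstitial macrophage and monocyte list, -0.35 and -0.15, of proliferation, -0.20 and -0.08, and of mitochondrially encoded mRNAs, -0.41 and -0.16. The club and secretory epithelium list had a median of 0.27, with Retnla, a protein of type 2 immune responses, at 1.44 ± 0.42, and its call ended with no batch term at 0.17. For these 5 lists adjusted p ran from 0.522 to 0.888 with an estimated correlation. Among readout genes, Col1a1 differed by log2 -0.28 ± 0.43, Col3a1 by -0.29 ± 0.39, Acta2 by 0.02 ± 0.40, Il6 by 0.99 ± 0.67 and Tgfb1 by -0.38 ± 0.22, each with an edgeR adjusted p of 1.

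Pla2g2d at -3.52 ± 0.68, Timd4 at -3.34 ± 0.72, Cd209b at -4.49 ± 0.97 and Dnase1l3, a nuclease of macrophages and dendritic cells, at -3.60 ± 0.88 had the smallest p, with edgeR adjusted p of 0.429, 0.583, 0.583 and 1. edgeR called 0 genes, with 562 at an unadjusted p under 0.05 (115 higher, 447 lower), and DESeq2 called 13, of which 8 were tested by edgeR. The November library is alone in its batch, so the estimate rests on the other 2 libraries of the group, and without DE library 2 the edgeR count was 14. The difference in Cd209b again rests on DE libraries 1 and 3.

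Preconditioning with pirfenidone in exposed lungs. RIC+DE+PFD lungs held less transcript of T cell, B cell and fat genes than DE lungs. All 16 T cell genes were lower, with a median log2 change of -0.63, Icos, a co-stimulatory receptor, at -1.48 ± 0.32 and 4 lower when adjusted over the list alone (camera adjusted p = 1.48e-07, and adjusted p = 0.718 with an estimated correlation). That call held under each other setting run for lists, with a median of -0.26 without DE library 1 and -1 without DE library 2. All 14 B cell genes were lower, with a median of -0.81 and Bank1, a B cell scaffold protein, at -1.61 ± 0.39, but at -0.63 and past no threshold without RIC+DE+PFD library 2. The adipocyte list had a median of -1.82, which was -0.92 without DE library 1 and -1.21 without RIC+DE+PFD library 3, both past no threshold. For the B cell and adipocyte lists adjusted p = 0.718 with an estimated correlation.

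The collagen and matrix list had a median of -0.33, with the crosslinking enzymes Lox at -0.86 ± 0.25 and Loxl2 at -0.83 ± 0.28 and the matrix protein Tnc at -1.38 ± 0.46 (camera adjusted p = 0.000151, and adjusted p = 0.718 with an estimated correlation). Without RIC+DE+PFD library 1 the median was -0.14 and did not pass. The ribosomal protein list, 0.45 with all libraries, was -0.16 without that library, where rho of deviation with gene length was -0.549. For ribosomal proteins adjusted p = 0.888 with an estimated correlation. Mitochondrially encoded mRNAs at -0.60, the mast cell, basophil and eosinophil list at -1.53, proliferation at -0.35, NRF2 at 0.16 and MHC class II at 0.33 were also called, ended without at least 1 library, and had adjusted p from 0.718 to 0.872 with an estimated correlation. Col1a1 differed by log2 -0.58 ± 0.38, Col3a1 by -0.68 ± 0.36, Acta2 by 0.22 ± 0.38, Hmox1 by 0.12 ± 0.24 and Ccn2 by 0.62 ± 0.30, with edgeR adjusted p of 0.527 or more.

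The smallest p belonged to Abcg3 at log2 -1.37 ± 0.23, Inpp4b, a lipid phosphatase, at -1.35 ± 0.23, Cttnbp2 at -1.49 ± 0.27 and Stab2 at -2.99 ± 0.54, with edgeR adjusted p of 0.0916 for the first pair and 0.097 for the other pair. edgeR called 0 genes, 1662 were at an unadjusted p under 0.05 (696 higher, 966 lower), and DESeq2 called 69, of which 58 were tested by edgeR. Without DE library 2 the edgeR count was 34 and without RIC+DE+PFD library 1 it was 15.

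Perconditioning with pirfenidone in exposed lungs. DE+PFD+RIC lungs held less transcript of T cell, ribosomal and mitochondrially encoded genes than DE lungs. Of the 16 T cell genes 14 were lower, 9 of them when adjusted over the list alone, with a median log2 change of -0.95 and Trac at -1.39 ± 0.33 (camera adjusted p = 1.37e-07, and adjusted p = 0.58 with an estimated correlation). Ribosomal proteins had a median of -0.68 and mitochondrially encoded mRNAs one of -0.96, with mt-Nd2 at -1.25 ± 0.45 (camera adjusted p = 1.37e-07 and 3.12e-05, and adjusted p = 0.657 with an estimated correlation for each). Those 3 calls held under each other setting run for lists, but the T cell median was -0.63 without DE library 1 and the ribosomal one -0.41 without RIC+DE+PFD library 1. Gene length moves with these groups too: Spearman's rho of deviation with length was 0.181, 0.453 and 0.286 in the DE+PFD+RIC libraries, of which the first pair are from March, against -0.275, -0.307 and -0.21 in DE. With the length trend removed, ribosomal protein deviations of 0.018, -0.885 and -0.31 in DE+PFD+RIC were 0.073, -0.616 and -0.205, and those of 0.287, 0.357 and 0.163 in DE were 0.048, 0.275 and 0.097.

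The B cell list had a median of -0.91, which was -0.39 and past no threshold without DE+PFD+RIC library 1, where the list level was -1.97. The mast cell, basophil and eosinophil list, median -1.78, the adipocyte list, -1.66, and the proliferation list, -0.38, ended without both libraries that stood apart, at -1.14, -0.62 and -0.13. TGF-beta pathway genes had a median of 0.37, with Smad4 at 0.56 ± 0.15 and Smad7 at 0.73 ± 0.27, at 0.17 with library quality weights and no longer called. Interferon response genes had a median of -0.32, with Cxcl9 at -2.35 ± 0.75, and without DE library 1 this median was -0.31, no longer past camera's threshold. MHC class II at -0.40, NRF2 at -0.27, erythroid at -0.62 and circadian clock at 0.54 were called too and ended under at least 1 setting. For the lists of this paragraph adjusted p ran from 0.61 to 0.657 with an estimated correlation.

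Fn1 differed by log2 0.91 ± 0.34, Timp1 by -1.03 ± 0.41 and Cyp1b1 by -1.29 ± 0.41 (edgeR adjusted p = 0.529 for each), and Col1a1 by 0.52 ± 0.42. The smallest p belonged to Pla2g2d at -3.19 ± 0.61, Ccl21a at -1.91 ± 0.37, Cd209b at -4.53 ± 0.89 and Timd4 at -3.28 ± 0.65, with an edgeR adjusted p of 0.284 for each. For Cd209b the difference rests on DE libraries 1 and 3, as above. In edgeR 0 genes passed, with 1600 at an unadjusted p under 0.05 (849 higher, 751 lower), DESeq2 called 14 (10 of them tested by edgeR), and without DE library 2 the edgeR count was 19.

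**Figure D3:**
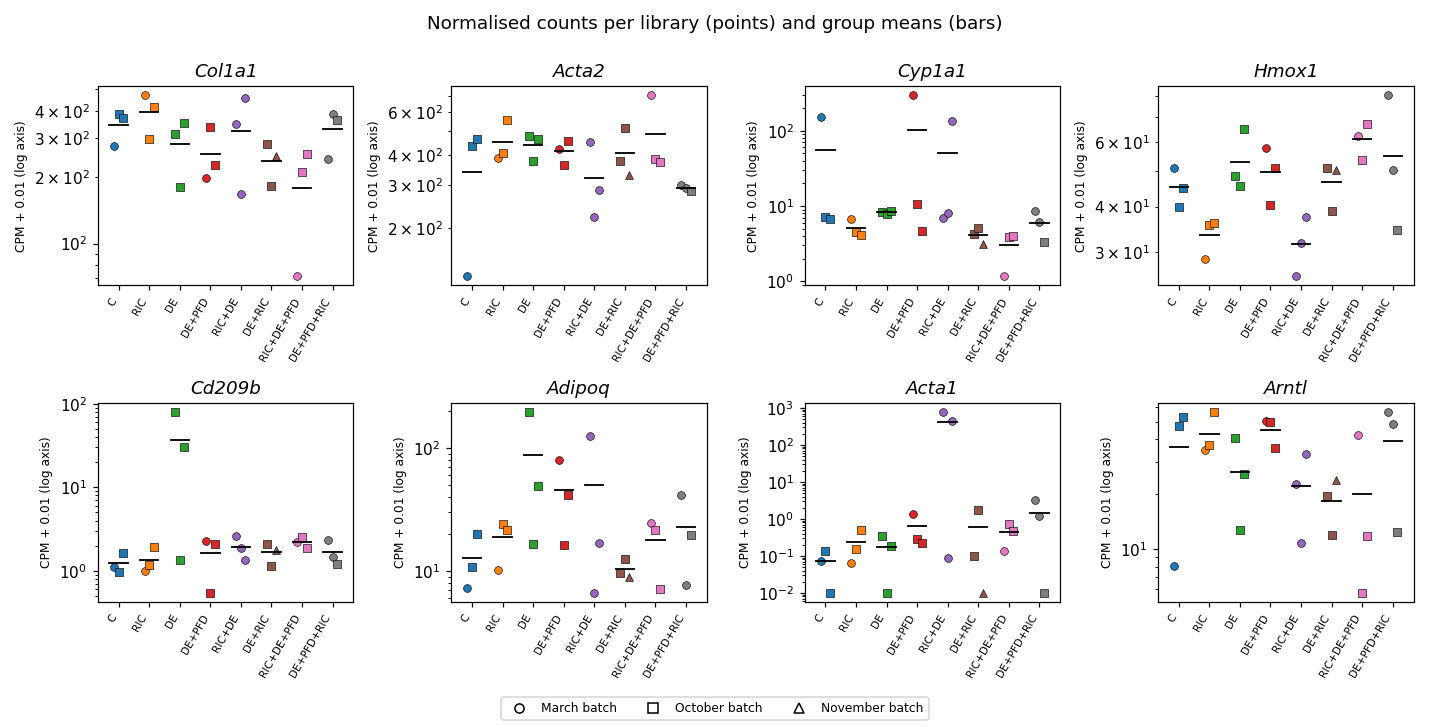
CPM plus 0.01 on a log axis for 8 genes, with a point per library, a bar at each group mean and marker shapes for batches; Cd209b, Adipoq, Acta1 and Arntl were chosen after their values were seen. Cd209b is at 80.1 and 30.6 CPM in DE 1 and DE 3 and at 2.59 or less in the other libraries, and Acta1, the actin of skeletal muscle, is at 778.8 and 451.9 CPM in RIC+DE 1 and RIC+DE 3.

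Whether each treatment undid the difference between DE and C was tested across genes. The DE libraries enter both sides with opposite sign, so a negative covariance arises with no effect at all, and 20 data sets simulated with no group effect gave that level. For DE+PFD the covariance of the log2 changes in DE minus C and in DE+PFD minus DE was -0.142 against a simulated -0.105, a difference of -0.0376 ± 0.0952 (SE over libraries left out in turn). The differences were -0.0456 ± 0.103 for RIC+DE, -0.0717 ± 0.151 for DE+RIC, -0.0281 ± 0.135 for RIC+DE+PFD and -0.0876 ± 0.114 for DE+PFD+RIC, all smaller than their errors. Without DE library 1 they were 0.0321 for DE+PFD, -0.0122 for RIC+DE, 0.0501 for DE+RIC, 0.0681 for RIC+DE+PFD and -0.009 for DE+PFD+RIC. The correlations, across genes that are not independent replicates, ran from -0.738 for DE+PFD+RIC to -0.488 for RIC+DE+PFD, beside simulated values of -0.569 and -0.547. With 3 DE libraries the shared group is too small to split, so part of any excess may come from the shared libraries. As edgeR called 0 genes between DE and C, with 582 at an unadjusted p under 0.05 and 17 calls by DESeq2 (10 of them genes edgeR tested), no set of exposure genes could be followed into the treated groups. Set against C, edgeR called 6 genes in RIC+DE, all higher and with a smallest adjusted p of 0.0499, with 1284 at an unadjusted p under 0.05. It called 0 in DE+PFD, DE+RIC, RIC+DE+PFD and DE+PFD+RIC against C, with 348, 375, 2969 and 341 at an unadjusted p under 0.05. Those were 1.99%, 2.14%, 17% and 1.95% of the genes. These contrasts were not run with DESeq2 or under the other settings.

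Preconditioning added to pirfenidone. RIC+DE+PFD lungs held less transcript of matrix and interferon genes than DE+PFD lungs, by camera with a preset correlation. The interferon response list had a median log2 change of -0.68, with the antiviral genes Rsad2 at -1.61 ± 0.34 and Mx2 at -1.18 ± 0.28, and 5 of 21 genes lower when adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.977 with an estimated correlation). Its median was -0.49 and past no threshold without RIC+DE+PFD library 2. The collagen and matrix list had a median of -0.46, with Fbn1, fibrillin, at -0.92 ± 0.28 and Eln, elastin, at -1.17 ± 0.44, and the matrix protease list one of -0.50, with Mmp14 at -0.76 ± 0.25 (camera adjusted p = 0.000401 and 0.00222, and adjusted p = 0.977 with an estimated correlation for each). Without RIC+DE+PFD library 1 the collagen median was -0.10 and did not pass, and without DE+PFD library 1 the protease median was -0.28 and did not pass. Ribosomal proteins had a median of 0.76, with 20 of 24 higher when adjusted over the list alone, and one of 0.02 without RIC+DE+PFD library 1, where rho of deviation with gene length was -0.549 (adjusted p = 0.977 with an estimated correlation for all libraries). Slc8a1, a sodium-calcium exchanger, was at 17.8 ± 6.43 CPM in RIC+DE+PFD and 43.8 ± 6.85 in DE+PFD (SD, n = 3), with an edgeR adjusted p of 0.0681. Cttnbp2 at log2 -1.49 ± 0.26, Trps1, a transcription factor, at -1.13 ± 0.21 and Adamts12, a matrix protease, at -2.33 ± 0.44 followed, with an edgeR adjusted p of 0.104 for each. edgeR called 0 genes, with 3022 at an unadjusted p under 0.05 (1858 higher, 1164 lower), and DESeq2 called 138, all tested by edgeR. The edgeR count was 20 without DE+PFD library 3, 15 without RIC+DE+PFD library 3, and 1 without either RIC+DE library 2 or DE+PFD+RIC library 3.

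Perconditioning added to pirfenidone. DE+PFD+RIC lungs held less transcript of interferon and antigen presentation genes than DE+PFD lungs. All 21 interferon response genes were lower, with a median log2 change of -0.80, and 13 of them when adjusted over the list alone (camera adjusted p = 1.9e-16, and adjusted p = 0.216 with an estimated correlation). Zbp1 differed by -1.71 ± 0.48 and Rsad2 by -1.06 ± 0.33. All 7 MHC class II genes were lower, with a median of -0.65, H2-Eb1 at -0.77 ± 0.24 and 5 lower when adjusted over the list alone (camera adjusted p = 2.71e-07, and adjusted p = 0.372 with an estimated correlation). Both calls held under each other setting run for lists, with an MHC class II median of -0.43 without DE+PFD library 2. The interferon list level was 0.727, 0.88 and -0.019 in DE+PFD, -0.271, -0.453 and -0.097 in DE+PFD+RIC, and 0.354, -0.201 and 0.03 in DE. Much of the interferon difference thus lies in DE+PFD libraries 1 and 2, and leaving out 1 library at a time does not remove both.

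The NK cell list had a median of -0.87, with Gzmb, a granzyme, at -1.52 ± 0.41 and Nkg7 at -1.32 ± 0.40, and one of -0.59, past no threshold, in the October libraries alone, where DE+PFD+RIC has 1 library (adjusted p = 0.395 with an estimated correlation for all libraries). NRF2 genes had a median of -0.35, with Nqo1 at -1.24 ± 0.45, and -0.18, past no threshold, without DE+PFD library 1. For this list adjusted p = 0.395 with an estimated correlation. The aryl hydrocarbon receptor list, median -0.28, was led by Cyp1a1 at -3.81 ± 1.27. Cyp1a1 was at 294.4 CPM in DE+PFD library 1, from March, and 10.7 and 4.68 in the others, from October. The list's median was -0.13 without DE+PFD library 1. Fibrillar collagen and matrix had a median of 0.20, with Fn1 at 0.84 ± 0.31, at 0.13 without DE+PFD+RIC library 2, and the TGF-beta pathway one of 0.22, at 0.14 without DE+PFD+RIC library 1, all past no threshold. The clock list had a median of 0.70, the mesothelium list 0.58 and the alveolar type 1 list 0.22. The medians of the lower lists were -0.40 for ribosomal proteins, -0.38 for transitional alveolar epithelium, -0.47 for erythroid, -1.17 for adipocyte, -0.68 for neutrophil, -0.37 for proliferation, -0.26 for cytokines and chemokines, -0.33 for ciliated epithelium, -0.43 for smooth muscle and myofibroblast and -0.91 for mast cell, basophil and eosinophil. The rho of deviation with gene length was 0.181, 0.453 and 0.286 in DE+PFD+RIC and 0.201, -0.0269 and -0.26 in DE+PFD. With the length trend removed, ribosomal protein deviations of 0.018, -0.885 and -0.31 in DE+PFD+RIC were 0.073, -0.616 and -0.205, and those of -0.201, -0.024 and 0.289 in DE+PFD were -0.135, -0.035 and 0.231. Of the 20 called, 18 ended under at least 1 setting, and adjusted p ran from 0.216 to 0.658 with an estimated correlation.

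Il18bp, an inhibitor of interleukin 18, at log2 -1.45 ± 0.31, the interferon-induced GTPase Tgtp2 at -2.01 ± 0.47, Colgalt2 at 0.69 ± 0.18 and H2-T22 at -1.03 ± 0.27 had the smallest p, with an edgeR adjusted p of 0.905 each. edgeR called 0 genes, 737 were at an unadjusted p under 0.05 (372 higher, 365 lower), and DESeq2 called 8, of which 1 was among the genes edgeR tested.

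Timing of conditioning without pirfenidone. DE+RIC lungs on average held less transcript of muscle genes and more of ribosomal, erythroid and epithelial genes than RIC+DE lungs. Cardiac muscle genes had a median log2 change of -2.01, with Ryr2 at -2.72 ± 0.55 and 8 of 13 lower when adjusted over the list alone, and skeletal muscle genes one of -3.80, with all 7 lower when adjusted over the list alone (camera adjusted p = 8.25e-10 and 0.00149). For these 2 lists adjusted p = 0.529 and 0.53 with an estimated correlation. Erythroid genes had a median of 1.29, with 6 of 9 higher when adjusted over the list alone, alveolar type 2 genes one of 0.78, with Sftpd at 1.02 ± 0.32, and transitional alveolar epithelium one of 0.67, with the keratin Krt8 at 0.80 ± 0.29 (camera adjusted p = 1.27e-05, 1.69e-05 and 0.00194, and adjusted p = 0.529 with an estimated correlation for each). Ribosomal proteins had a median of 1.01 and inflammatory cytokines and chemokines one of 0.58, with Il6 at 2.53 ± 0.81 and the siderophore-binding protein Lcn2 at 1.59 ± 0.51 (camera adjusted p = 1.46e-09 and 0.00348, and adjusted p = 0.53 and 0.529 with an estimated correlation). These 7 calls held under each other setting run for lists (October alone has no RIC+DE). Without RIC+DE+PFD 1 the ribosomal and cytokine medians were 0.59 and 0.37. The skeletal muscle median was -5.76 without RIC+DE 2, and its difference rests on RIC+DE 1 and 3. Spearman's rho of deviation with gene length was 0.376 to 0.465 in the RIC+DE libraries and -0.222, -0.162 and 0.0934 in DE+RIC. With the length trend removed, ribosomal protein deviations of 0.05, 0.208 and -0.141 in DE+RIC were 0.036, 0.2 and -0.13, and those of -0.956, -0.619 and -0.555 in RIC+DE were -0.85, -0.384 and -0.434. Club and secretory epithelium at 0.86, ciliated epithelium at 0.64, NRF2 at 0.37 and the unfolded protein response at 0.51 had medians of 0.32, 0.16, 0.06 and 0.30 with no batch term and were then not called. MHC class II at 0.49 and mitochondrially encoded mRNAs at 1.11 were called too and ended under at least 1 setting. For these 6 lists adjusted p ran from 0.529 to 0.714 with an estimated correlation. The smallest p belonged to the muscle genes Rbm20 at log2 -3.92 ± 0.70, Xirp2 at -5.37 ± 0.96 and Rnf207 at -4.45 ± 0.84 and to Retnla at 2.73 ± 0.50, with an edgeR adjusted p of 0.0717 each. edgeR called 0 genes, with 2399 at an unadjusted p under 0.05 (1300 higher, 1099 lower), and DESeq2 called 121, of which 116 were tested by edgeR. The groups share no batch, and the edgeR count was 161 with no batch term, 124 without RIC+DE library 2 and 27 without DE+PFD library 1.

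Timing of conditioning with pirfenidone. Compared with RIC+DE+PFD lungs, DE+PFD+RIC lungs held less transcript of ribosomal, antioxidant and MHC class II genes and more of matrix genes. All 24 ribosomal protein genes were lower, each also when adjusted over the list alone, with a median log2 change of -1.17 (camera adjusted p = 1.87e-11). The NRF2 and antioxidant list had a median of -0.46, with Sod1, superoxide dismutase, at -1.34 ± 0.33 and 8 of 22 lower when adjusted over the list alone, and the MHC class II list one of -0.82, with H2-DMa at -1.13 ± 0.31 and 6 of 7 lower when adjusted over the list alone (camera adjusted p = 0.0012 and 0.00137). For these 3 lists, whose calls held under each other setting run for lists, adjusted p = 0.957 with an estimated correlation. Without RIC+DE+PFD library 1 the ribosomal median was -0.25 and the MHC class II median -0.47. In that library rho of deviation with gene length was -0.549, against 0.181 to 0.453 in DE+PFD+RIC. It held 1902 CPM of Sod1 against 680.7 and 719.0 in the others of its group. The collagen and matrix list had a median of 0.83, with Fbn1 at 111.4 ± 35.8 CPM against 45.8 ± 16.6 (SD, n = 3) and Lox at log2 0.97 ± 0.26, and one of 0.22, past no threshold, in the October libraries alone, where DE+PFD+RIC has 1 library (adjusted p = 0.957 with an estimated correlation for all libraries). Without RIC+DE+PFD library 1 it was 0.24 and still called. Without RIC+DE+PFD library 1 the TGF-beta pathway median of 0.51 was 0.09 and the vascular endothelium median of 0.76 was 0.06, neither past a threshold. For these lists adjusted p = 0.957 and 0.998 with an estimated correlation. Cacna1d, a calcium channel, at 1.37 ± 0.24, Zfp462 at 1.31 ± 0.25, the clock gene Clock at 1.09 ± 0.22 and Cttnbp2 at 1.29 ± 0.26 had the smallest p, with an edgeR adjusted p of 0.0658 each. edgeR called 0 genes, 4904 were at an unadjusted p under 0.05 (1758 higher, 3146 lower), and DESeq2 called 2494, all tested by edgeR. The edgeR count was 1081 without RIC library 1, 4210 without RIC+DE+PFD library 2 and 2563 without RIC+DE+PFD library 3, and 0 without RIC+DE+PFD library 1.

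Whether pirfenidone changed the effect of preconditioning was tested as the interaction of both. Ribosomal protein genes had a median interaction of log2 1.82, all 24 also higher when adjusted over the list alone, and mitochondrially encoded mRNAs one of 1.72 (camera adjusted p = 8.31e-14 and 0.000667). Both calls held under each other setting run for lists (not October libraries alone, where RIC+DE has none), but without RIC+DE+PFD library 1, where rho of deviation with gene length was -0.549, the medians were 0.66 and 0.89. The collagen and matrix list had a median of -0.85, with Fbn1 at -1.30 ± 0.45, the NRF2 list one of 0.62, with Hmox1 at 1.29 ± 0.37, and the T cell list one of 0.79, with Cd3g at 1.74 ± 0.44 (camera adjusted p = 0.0074, 0.0072 and 0.0439). For these 5 lists adjusted p = 0.849 with an estimated correlation. The collagen median was -0.15 without RIC+DE+PFD library 1, the NRF2 median 0.28 with no batch term and the T cell median 0.36 without DE library 1, none of them past camera's threshold. Slc8a1 at -1.76 ± 0.33, Ccl21a at 2.59 ± 0.50, Cacna1d at -1.75 ± 0.37 and Ano9 at -2.54 ± 0.54 had the smallest p, with an edgeR adjusted p of 0.0742 each. edgeR called 0 genes, with 4753 at an unadjusted p under 0.05 (3181 higher, 1572 lower), and DESeq2 called 1912, of which 1911 were tested by edgeR. The edgeR count was 1650 without RIC library 1, 2880 and 2031 without RIC+DE+PFD library 2 or 3, 17 without RIC+DE library 2, 1 without DE library 2 and 0 without RIC+DE+PFD library 1.

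For the interaction of perconditioning with pirfenidone, T cell genes had a median of log2 0.57, all 16 above 0, with the transcription factor Tcf7 at 1.13 ± 0.37, and cardiac muscle genes one of 1.15 (camera adjusted p = 5.64e-06 and 1.03e-05). The MHC class II list had a median of -0.53, the ciliated epithelium list one of -0.54 and the erythroid list one of -0.64 (camera adjusted p = 0.000622, 5.76e-06 and 0.00178). For these 5 lists, whose calls held under each other setting run for lists, adjusted p = 0.483 with an estimated correlation. The T cell median was 0.21 without DE library 1, 0.33 without DE+PFD+RIC library 3, and 0.88 without either DE library 2 or DE+PFD+RIC library 1. Interferon response genes had a median of -0.75, with Gbp2 at -1.62 ± 0.65, and one of -0.39, past no threshold, in the October libraries alone, where DE+PFD+RIC has 1 library (camera adjusted p = 3.03e-08 for all libraries, and adjusted p = 0.483 with an estimated correlation). Capn11, a protease, at log2 -6.56 ± 1.40 (edgeR adjusted p = 0.938), Retnla at -2.54 ± 0.59, Pla2g2d at 3.37 ± 0.87 and Derl3, a gene of plasma cells, at 2.76 ± 0.79 (adjusted p = 1 for each) had the smallest p. In edgeR 0 genes passed, with 467 at an unadjusted p under 0.05 (262 higher, 205 lower), and DESeq2 called 6, of which 1 was tested by edgeR, while the edgeR count was 2 without DE library 2.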

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

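Each test of a technical or biological explanation in this part was chosen after the result it measures was seen. The interaction of pirfenidone with the timing of conditioning was a planned test. It asks whether the effect of conditioning differed with and without the drug, and 26 lists differed by camera with a preset correlation, 0 with an estimated one.

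For preconditioning 9 lists differed, each with an adjusted p of 0.849 with an estimated correlation. Median log2 interactions were 1.82 for ribosomal proteins, 1.72 for mitochondrially encoded mRNAs, 1.07 for erythroid, 0.83 for the unfolded protein response, 0.79 for T cell, 0.77 for inflammatory cytokines and chemokines and 0.62 for NRF2 and antioxidant. They were -0.85 for fibrillar collagen and matrix and -0.54 for the TGF-beta pathway. Of these calls 7 ended under at least 1 setting besides the estimated correlation. Without RIC+DE+PFD library 1 the medians were -0.15 for collagen, -0.16 for the TGF-beta pathway, 0.33 for erythroid and 0.27 for cytokines and chemokines, all past no threshold, and 0.66 for ribosomal proteins, 0.89 for mitochondrially encoded mRNAs, 0.52 for the unfolded protein response and 0.41 for NRF2. The T cell median was 0.36 without DE library 1 and 0.52 without DE+PFD library 3, the NRF2 median 0.28 with no batch term, and the unfolded protein response median 0.86 without RIC+DE+PFD library 3, none past a threshold.

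For perconditioning 17 lists differed, with adjusted p from 0.483 to 0.817 with an estimated correlation. Higher medians were 1.34 for adipocyte, 1.15 for cardiac muscle, 0.79 for both B cell and plasma cell, 0.71 for mesothelium and 0.57 for T cell. Lower medians were -0.91 for NK cell, -0.77 for neutrophil, -0.75 for interferon response, -0.64 for erythroid, -0.54 for ciliated epithelium, -0.53 for MHC class II, -0.42 for both transitional alveolar and club and secretory epithelium, -0.29 for ribosomal proteins, -0.27 for NRF2 and -0.24 for the aryl hydrocarbon receptor list. Of these calls 12 ended under at least 1 setting besides the estimated correlation. In the October libraries alone, where DE+PFD+RIC has 1 library, the medians were -0.39 for interferon, -0.53 for NK cell, -0.10 for neutrophil and 0.06 for mesothelium. Other calls ended without 1 library, among them adipocyte at 0.41 without DE 1 and at 0.79 without either DE+PFD 2 or DE+PFD+RIC 1, plasma cell at 0.23 without DE 1 and 0.16 without DE+PFD+RIC 3, and B cell at 0.32 without DE+PFD+RIC 3. Mesothelium ended at 0.45 without DE+RIC 2 and 0.42 without DE+PFD+RIC 1, neutrophil at -0.49 without DE+PFD 1 and -0.50 without DE+PFD+RIC 2, transitional alveolar epithelium at -0.18 without DE+PFD+RIC 3, and club and secretory epithelium at -0.12 without DE+PFD 3. Ribosomal proteins ended at -0.13 without either DE+PFD 3 or RIC+DE+PFD 1 and at -0.08 without DE+PFD+RIC 2, NRF2 at -0.09 and the aryl hydrocarbon receptor list at -0.18 without DE+PFD 1. Calls that held while the median moved were adipocyte at 2.13 without DE 2, B cell at 0.39 without DE 1 and 1.33 without DE+PFD+RIC 1, ribosomal proteins at -0.48 without DE+PFD 1 and -0.47 without DE+PFD+RIC 1, transitional alveolar epithelium at -0.71 without DE+PFD+RIC 1, club and secretory epithelium at -0.67 without DE+PFD 2 and the aryl hydrocarbon receptor list at -0.49 without DE+RIC 1. The T cell median was 0.21 without DE library 1, 0.33 without DE+PFD+RIC library 3, and 0.88 without either DE library 2 or DE+PFD+RIC library 1.

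RIC+DE+PFD library 1 stood apart from the other 23, with ribosomal protein genes at 2.07 log2 units above the mean of the libraries where the next highest was 0.382. Its deviations fell with gene length (Spearman's rho -0.549), while those of the other 8 March libraries rose with it (0.181 to 0.465). After the length trend was removed its ribosomal protein genes stayed at 1.47 against at most 0.275 elsewhere. Lost long transcripts and another mix of cells stay open, since the ribosomal level is itself what set the library apart and cannot test them. The other libraries of its group, at 0.191 or less, argue against the treatment. RNA quality in that library may still have a part and was not measured here.

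DE libraries 1 and 3 stood apart in Cd209b, a gene of lymphoid tissue, at 80.1 and 30.6 CPM, and had adipocyte levels of 3.58 and 1.60 against -0.26 in DE library 2, though RIC+DE library 1 was at 3.04 and DE+PFD library 1 at 1.70. The other October libraries had at most 2.55 CPM of Cd209b, which argues against that batch. Lymph node and fat taken with the lung may be the source: 2 of the T cell, B cell and adipocyte lists lay above each control library in both. An effect of diesel exhaust stays open as well, since DE library 2, at 1.34 CPM of Cd209b, is the 1 other exposed library without treatment and cannot exclude it. The same DE libraries enter each comparison of a treated group with DE. Lower Cd209b, T cell, B cell and adipocyte levels in those comparisons are therefore not independent results for each treatment.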

How the results depend on the processing

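Quality weights, March alone and the fit without both libraries that stood apart were chosen after the results were seen. In edgeR 0 genes passed in each of the 13 comparisons, which leave out the treated groups against C, with 209 to 4904 at an unadjusted p under 0.05 and 4 to 2494 calls by DESeq2. Those counts stayed at 0 with DESeq2's size factors, with a filter of CPM 1 in 3 libraries and without both libraries that stood apart. The cause of the changes below was not tested.

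In the order DE minus C, RIC minus C, DE+PFD minus DE, RIC+DE minus DE, DE+RIC minus DE, RIC+DE+PFD minus DE, DE+PFD+RIC minus DE, RIC+DE+PFD minus DE+PFD, DE+PFD+RIC minus DE+PFD, DE+RIC minus RIC+DE, DE+PFD+RIC minus RIC+DE+PFD and the interactions with preconditioning and perconditioning, the counts with no filter on low counts were 199, 63, 180, 1129, 229, 347, 306, 674, 131, 849, 1959, 2179 and 164. In the same order DESeq2, run without that filter, called 17, 4, 15, 80, 13, 69, 14, 138, 8, 121, 2494, 1912 and 6, of which 10, 0, 5, 77, 8, 58, 10, 138, 1, 116, 2494, 1911 and 1 were genes edgeR tested. With no batch term the counts were 1, 0, 0, 102, 3, 9, 9, 0, 0, 161, 941, 1662 and 0.

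With the libraries of the compared groups alone the counts were 3833 in RIC+DE minus DE, 25 in RIC+DE+PFD minus DE, 2409 in DE+RIC minus RIC+DE and 1334 in the interaction with preconditioning. RIC+DE shares no batch with DE or DE+RIC, so the fits behind 3833 and 2409 also lack the batch term, and batch and group cannot be told apart in them. In October libraries alone they were 78 in RIC+DE+PFD minus DE, 1 in DE+PFD+RIC minus DE, 8 in RIC+DE+PFD minus DE+PFD and 1 in the interaction with perconditioning. DE+PFD+RIC has 1 October library, assumed to vary like the other groups. In March libraries alone they were 4798 in RIC+DE+PFD minus DE+PFD and 6672 in DE+PFD+RIC minus RIC+DE+PFD. There RIC+DE+PFD is the 1 library that stood apart (quality weight 0.0463) and DE+PFD has 1 library too, each assumed to vary like the other groups, so both counts rest on that 1 library. With the November library in the October batch they were 2 in DE+RIC minus DE, 1 in RIC+DE+PFD minus DE+PFD and 87 in DE+RIC minus RIC+DE. With quality weights they were 1 in RIC+DE minus DE, 2 in RIC+DE+PFD minus DE, 4 in DE+PFD+RIC minus DE, 3 in RIC+DE+PFD minus DE+PFD and 207 in DE+PFD+RIC minus DE+PFD.

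Libraries with the same replicate number did not deviate together on average: the mean correlation was -0.0064 over 84 pairs (-0.389 to 0.412, 16 above 0.1) and 0.00262 for other pairs. After group and batch were removed it was -0.0421 over 77 pairs (-0.648 to 0.412, 15 above 0.1) and 0.0201 for other pairs. A low mean cannot exclude that some numbers pair the animals. The replicate block with the batch term gave 13 genes in RIC+DE minus DE, 166 in DE+RIC minus RIC+DE and 6 in the interaction with preconditioning. The replicate block without the batch term gave 21 in RIC+DE minus DE, 1 in DE+RIC minus DE and 121 in DE+RIC minus RIC+DE.

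Leaving out each library in turn gave 0 to 15 genes in DE minus C, 0 to 13 in DE+PFD minus DE, 0 to 54 in RIC+DE minus DE, 0 to 14 in DE+RIC minus DE, 0 to 34 in RIC+DE+PFD minus DE, 0 to 19 in DE+PFD+RIC minus DE and 0 to 20 in RIC+DE+PFD minus DE+PFD. It gave 0 to 124 in DE+RIC minus RIC+DE, 0 to 4210 in DE+PFD+RIC minus RIC+DE+PFD, 0 to 2880 in the interaction with preconditioning, 0 to 2 in that with perconditioning, and 0 in both RIC minus C and DE+PFD+RIC minus DE+PFD. The covariance differences ran from -0.0821 to 0.0321 for DE+PFD, -0.127 to 0.0501 for DE+RIC and -0.103 to 0.0681 for RIC+DE+PFD, each turned without DE library 1, and from -0.11 to -0.00386 for RIC+DE and -0.133 to -0.009 for DE+PFD+RIC.

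Of 162 list calls by camera with a preset correlation, a mean of 12.5 per comparison, 43 held under each setting run for lists but the estimated correlation, which ended them all, a mean of 0. Lists were not run with DESeq2, its size factors, the other filters, the compared groups alone, the block without the batch term or March alone, and in October alone for 10 of the 13 comparisons. The rotation test fry, which called 0 lists in a given direction, called 1 list when changes both ways count in each of RIC+DE minus DE (cytokines and chemokines, fry adjusted p = 0.0324), DE+PFD+RIC minus DE (T cell, 0.0318) and DE+PFD+RIC minus RIC+DE+PFD (NRF2, 0.0147). Medians turned in DE minus C for immediate early genes without DE library 2 (0.07, with -0.43 at the other end of the range over libraries left out), B cell without DE library 1 (-0.13, other end 0.49) and without both libraries apart (-0.15), and smooth muscle and myofibroblast in October alone (-0.04) and without C library 1 (-0.05, other end 0.52). The glucocorticoid response median turned there too, at -0.06 without C library 2. In RIC minus C the median turned for B cell without RIC library 2 (-0.05, other end 0.51) and for mesothelium in October alone (0.02) and without RIC library 1 (0.03). It also turned there for the aryl hydrocarbon receptor list in October alone (0.03). Ribosomal proteins in RIC+DE+PFD minus DE were at -0.16 in October alone, without both libraries apart and without RIC+DE+PFD library 1 (other end 0.84), and at -0.07 with quality weights. Of these settings only October alone called the list lower (camera adjusted p = 0.00583). Camera's direction turned, with the median on the same side of 0, for vascular endothelium in DE minus C without both libraries apart (-0.01), ciliated epithelium in DE+PFD minus DE without DE library 1 (0.06, other end 0.44), mitochondrially encoded mRNAs in DE+RIC minus DE with no batch term (-0.26), and in October alone for ribosomal proteins in RIC+DE+PFD minus DE+PFD (0.01) and mesothelium in DE+PFD+RIC minus DE+PFD (0.03). Tgfb1 in RIC+DE minus DE, at 0.003 ± 0.24 (edgeR adjusted p = 0.996), was at -0.53 with the compared groups alone and so no batch term (0.0368), and at -0.54 with all libraries and no batch term (0.185). Its adjusted p ran from 0.0368 to 1 over the alternatives.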

Other observations

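Each test and each gene in this part was chosen after its values were seen, the splits' statistic included. Genes of the circadian clock varied widely between the lungs. Arntl, the activator at the core of the clock, ran from 5.73 CPM in RIC+DE+PFD library 2 to 56.5 CPM in DE+PFD+RIC library 1. It went against Dbp and Per3, clock outputs that peak when Arntl is low: over the 24 libraries Pearson's r was -0.829 with Dbp and -0.838 with Per3 (permutation p = 1.0e-05 for each, the smallest that 100000 permutations can give). With Nr1d1, a repressor of Arntl, r was -0.485 (permutation p = 0.0167). Spearman's rho was -0.82, -0.836 and -0.527 for Dbp, Per3 and Nr1d1.

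Within the 14 October libraries r was -0.904 with Dbp, -0.939 with Per3 and -0.552 with Nr1d1. Within the 9 March libraries it was -0.8, -0.823 and -0.454 (exact permutation p = 0.00894, 0.00536 and 0.229), so that with Nr1d1 did not pass there. A shared scale or depth would make Arntl and Per3 rise together, and r was -0.838. Different times of day at collection stay open: the r of -0.829 with Dbp restates the pattern on genes chosen for it and cannot support them. The treatment groups held 31.5% of the variance of Arntl (permutation p = 0.426), which leaves them open. The labels give no time of collection.

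Cyp1a1, an enzyme induced by aromatic hydrocarbons, was at 153.3 CPM in C library 1, 294.4 in DE+PFD library 1 and 136.6 in RIC+DE library 3, and at 10.7 CPM or less in the other 21 libraries. The exposed groups had no common rise. The libraries with high values are all from March, although other March libraries were low. DE has no March library, so a rise in DE within that batch cannot be judged. Acta1, the actin of skeletal muscle, was at 778.8 and 451.9 CPM in RIC+DE libraries 1 and 3 and at 3.19 CPM or less in the rest.

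Each comparison of 2 groups was set against the other splits of its 6 libraries by the number of genes at an unadjusted p under 0.05 in edgeR, as the number past the threshold was 0 in each. Of 10 splits, 3 gave at least as many in DE minus C, 7 in RIC minus C, 4 in DE+PFD minus DE, 1 in RIC+DE minus DE, 5 in DE+RIC minus DE, 6 in RIC+DE+PFD minus DE and 1 in DE+PFD+RIC minus DE. The count was 4 in RIC+DE+PFD minus DE+PFD, 5 in DE+PFD+RIC minus DE+PFD, 1 in DE+RIC minus RIC+DE and 2 in DE+PFD+RIC minus RIC+DE+PFD. With 10 splits a share under 0.05 cannot be reached. In RIC+DE minus DE and DE+RIC minus RIC+DE the groups share no batch, so only the real split keeps March libraries apart from the rest. Its rank there does not tell batch from treatment. In that order, the real numbers and the highest of the other splits were 582 and 1069, 209 and 484, 492 and 1219, 3006 and 1334, 562 and 1058, 1662 and 3463, 1600 and 1571, 3022 and 3660, 737 and 1550, 2399 and 1187, and 4904 and 5277. DESeq2, run without the filter on low counts, called 17, 4, 15, 80, 13, 69, 14, 138, 8, 121 and 2494 genes for the real groups.

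For the interaction with preconditioning 1 of 30 splits, the real one, gave as many as 4753 genes, with 4237 as the highest other. The drawn splits mix batches, while the real groups set RIC+DE libraries, all from March, against DE libraries, all from October. The share of splits therefore does not tell chance or batch from treatment here. For the interaction with perconditioning 12 of 30 splits gave at least the real 467 genes, with 1174 as the highest, so chance is not excluded. DESeq2 called 1912 and 6 genes in these interactions, and edgeR 0.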
